A study of Glycine max with 2 samples.

How the data were processed

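RNA abundance was measured in pedicels of soybean (Glycine max, cultivar Fukuyutaka) at 51 and 66 days after flowering (DAF). There was 1 single-colour Agilent array of design 016772 per time point. Per the labels, total RNA was isolated by an SDS, phenol and lithium chloride method, amplified to cRNA and labelled with Cy3. Each array held 42748 soybean probes, with 1 probe per accession, so the probe was the unit throughout.

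The deposited scanner files gave a processed signal intensity for each spot. Per the file headers, this intensity was background-subtracted and spatially detrended within the array by Agilent Feature Extraction 10.7.1.1, with a surrogate value where a spot was not above background. The labels name version 9.5.1.1 of the same software, and the difference could not be resolved. No scaling between the arrays had been applied to these values. The authors also deposited a table of intensity values on a linear scale, in which both arrays held the same set of sorted values, as quantile normalization gives. The same scanner files gave raw mean spot intensity and local background intensity, deposited without normalization.

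The log2 of the deposited processed intensity was computed here, and the 75th percentile of each array's soybean probes was subtracted. Spots called outliers by the scanner software were left out, which concerned 6 probes. A probe was called measured when it was well above background on both arrays and not saturated on both. No soybean probe was saturated on either array. Differences are log2 values at 66 DAF minus those at 51 DAF, and a probe was counted as higher or lower from 2-fold on. For a probe above background on 1 array only, the difference was a bound, taken against the higher of its own dim value and the detection floor of the dim array. That floor was the signal 7.70 at 51 DAF and 8.96 at 66 DAF, which correspond to normalized log2 values of -2.62 and -6.44.

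With 1 array per time point no test between the time points was possible, and no p-value was computed. The only technical error came from 10 spike-in control probes with 320 spots on each array and from the scanner's own error model. Gene names were taken from the titles that the array's annotation gives. None of the accessions was found in the reference table (0 matches), and the annotation gave no genome positions, so none are printed. Many titles name the gene of another plant to which the soybean sequence was matched.

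The following 31 gene lists were matched to the titles by search patterns: monolignol synthesis, lignin polymerisation, secondary wall polysaccharides, aquaporins, cell wall loosening and separation, ethylene, abscisic acid, auxin, photosynthesis, senescence and chlorophyll breakdown, autophagy, programmed cell death proteases and nucleases, late embryogenesis abundant (LEA) and dehydration proteins, heat shock and chaperones, flavonoid and isoflavonoid synthesis, pathogenesis related proteins, WRKY factors, NAC factors, MYB factors, sugar transport and sucrose breakdown, amino acid remobilisation, cytosolic ribosomal proteins, histones and cell cycle, tubulin and actin, proteasome and ubiquitin, seed proteins, vegetative storage and pod wall proteins, nodule proteins, phloem proteins, cambium and xylem identity, and wax, cutin and suberin. The seed, pod wall and nodule lists stand for other tissues. For each list the members at least 2-fold higher or lower were counted among measured probes. The median difference was ranked among the medians of 10000 random lists of the same size, drawn from measured probes matched on mean expression in 20 bins. A list was called outside the random lists below percentile 2.5 or above percentile 97.5. The rank describes these 2 arrays only, and 1.55 of 31 lists are outside by chance if probes are independent. Intervals of medians are 95% intervals over probes from binomial order statistics. They cover neither plants nor arrays. The monolignol and flavonoid lists shared 12 measured probes, which carry a family title of cinnamoyl-CoA and flavonol reductases. The secondary wall and the cambium and xylem lists shared 1, and the ethylene and auxin lists shared 1.

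Named genes followed a rule. They are the 8 probes with a descriptive title with the largest difference in each direction among measured probes, and the 4 with the largest bound in each direction among probes measured on 1 array. In the lists described gene by gene they are up to 3 measured members with the largest differences of at least 2-fold in each direction. Members whose title does not belong to the list were passed over in naming and removed in an alternative. The lists of tubulin and actin, LEA and dehydration proteins, heat shock and chaperones, WRKY factors, MYB factors, autophagy, cytosolic ribosomal proteins, proteasome and ubiquitin, and wax, cutin and suberin were summarised without examples. For some other lists only the leading members in each direction are printed. The lists, the naming rule, the 2-fold threshold and 12 alternatives were fixed before the data were examined. A breakdown of wall formation by enzyme, 7 lists of genome and other-organism titles, and 7 further alternatives were added after the values were seen.

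The alternatives fixed beforehand were normexp background correction with an offset of 50, quantile, median and loess normalization, spike-in scaling, the authors' table, no filter, a stricter filter, thresholds of 1.5-fold and 4-fold, outlier spots kept, and a mean over the probes of an accession. Those added later were a floor common to both arrays, probes measured on either array, a correction for GC content, a correction for the clone collection and read end of the probe, removal of wrongly matched list members, random lists of titled probes, and identical titles averaged.

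The calculation was tested on simulated data for the comparison of 66 with 51 DAF, in which 200 probes were changed and 21984 probes passed through the step. All 34 probes lowered 8-fold and all 34 lowered 4-fold were found at least 2-fold lower. All 33 probes raised 4-fold and 23 of 33 raised 8-fold (69.7%) were found at least 2-fold higher. At a true 2-fold difference, 10 of 33 lowered and 13 of 33 raised probes passed the 2-fold threshold. Of 21794 unchanged probes, 0 were called higher and 24 (0.110%) lower. The simulated 51 DAF array was the 66 DAF array scaled down, with an assumed noise added. Changed probes were drawn from those well over the floor. The simulation holds no difference between plants, RNA quality or handling, so these shares are not error rates of the real comparison. Of 200 random lists 6 (3.0%) fell outside the middle 95%, and a list of 50 probes raised 2-fold reached percentile 100.

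The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for background correction and normalization.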

Results

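The data describe RNA in the pedicel, the stalk that joins the pod to the stem, of soybean plants of the cultivar Fukuyutaka. Pedicels taken 51 days after flowering (DAF) and pedicels taken 66 DAF were each hybridised to 1 single-colour array. There were no replicates, so no difference was checked against a replicate, and the number of arrays limits the precision. Per the labels, pedicels were sampled 7 times from 51 to 81 DAF at steps of 5 days. The other times, and any measurements of lignin or of water transport, were not analysed here. Of the 42748 soybean probes, 21127 carried a title that describes a gene product.

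Soybean probes were much dimmer on the 51 DAF array than on the 66 DAF array. The 75th percentile of the background-corrected signal was 47.5 at 51 DAF and 776 at 66 DAF, a 16.3-fold difference. Local background was alike, with a median of 60 at 51 DAF and 61.5 at 66 DAF. At 51 DAF 22937 probes (53.7%) were well above background, and at 66 DAF 33194 (77.7%) were. The spike-in controls, synthetic RNAs added to the labelling reaction, went the other way: the 7 that were above background on every spot were 1.74-fold brighter at 51 DAF, with a mean log2 difference of -0.80 ± 0.08 (SD over the 7 probes). Replicate spots of a spike-in differed little, with a median SD of 0.05 at 51 DAF and 0.04 at 66 DAF on the log2 scale.

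**Figure D1:**
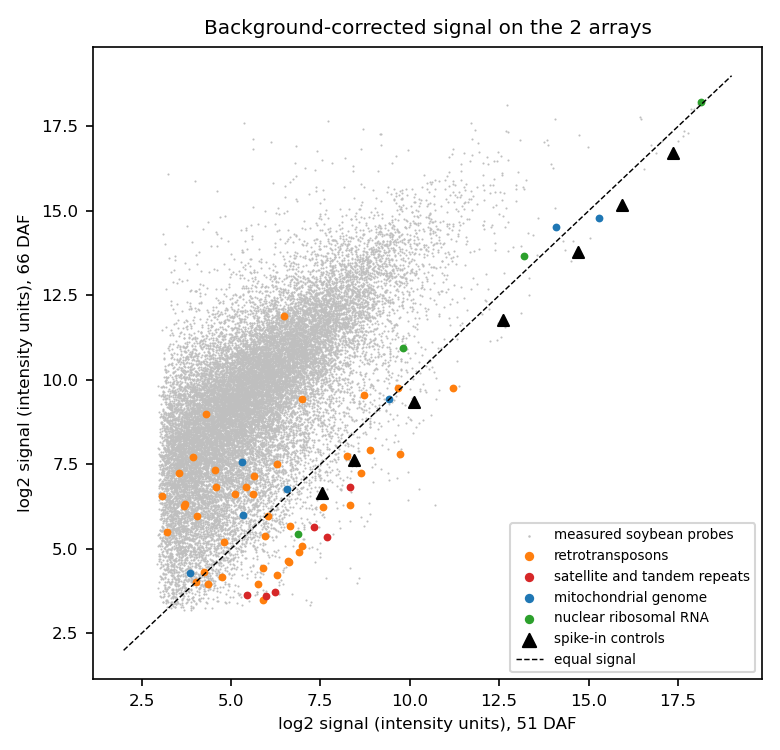
Background-corrected log2 signal of each measured soybean probe at 51 DAF (horizontal axis) and 66 DAF (vertical axis), in intensity units, with probes of repeat, mitochondrial and ribosomal RNA titles in colour and the 7 spike-in controls above background on every spot as triangles. Most soybean probes lie above the dashed line of equal signal, by a median of 3.81 log2 units, while these 7 spike-ins lie below it.

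The comparison of 66 with 51 DAF asks which transcripts of the pedicel differed while the seeds matured, in a study about lignin in the xylem vessels of the pedicel and the passage of water through it. Relative to the 75th percentile of each array, enzymes of monolignol synthesis, which make the building blocks of lignin, were higher at 66 DAF, with 31 of 53 measured probes at least 2-fold higher and 9 lower. Genes of photosynthesis were higher too, with 71 of 103 probes at least 2-fold higher. Genes of secondary wall polysaccharides were lower, with 20 of 31 probes at least 2-fold lower, and so were genes of cambium and xylem identity, with 20 of 30 lower. Aquaporins, the water channels of the plasma membrane and the vacuole, went both ways, with 7 of 35 higher and 14 lower. After correction for GC content, which also re-centred the differences, 14 were higher and 12 lower. Of the 22667 probes measured on both arrays, 4194 were at least 2-fold higher at 66 DAF, 7257 at least 2-fold lower and 11216 within 2-fold. At a threshold of 8-fold, 400 were higher and 2087 lower.

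The balance between higher and lower depended on the scaling and the floor. Of the probes that differed, 36.6% were higher with the 75th percentile. Centring on the median of all probes shifted every difference by 0.38 log2 and gave 6138 higher and 5819 lower (51.3% higher). Scaling on the spike-ins shifted every difference by 4.83 log2 and gave 21672 higher and 69 lower (99.7% higher), which turns every negative median of the 31 gene lists positive. Normexp background correction moved the median of the measured probes by -0.11. A probe could be followed down to a normalized log2 signal of -6.44 at 66 DAF but only to -2.62 at 51 DAF. Among the 18859 probes above a floor common to both arrays 4194 were higher and 3757 lower. This floor could not change the number of higher probes. All directions below are therefore relative to the 75th percentile of each array, unless another scaling or a correction is named.

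The genes with the largest differences included defence, wall and transport genes on the higher side and cellulose synthases on the lower side. The largest differences upward were a thaumatin-like protein MDTL1, of a family of defence proteins (BI321247.1_293, log2 difference 7.86, 233-fold), and a pectinesterase-2 (BI699879.1_415, 7.20), an enzyme that removes methyl groups from wall pectin. A second pectinesterase, PE3 (BI970632.1_624), was higher by 6.31. The stem-specific protein TSJT1 (BG839033.1_721) was higher by 7.17, the branched chain aminotransferase BCAT1 (GMFL01-45-P09-R_347) by 6.82 and the defence protein PR1a (GMFL01-30-H16-F_101) by 6.28. A probe titled amino acid transporters (CO984079.1_482) was higher by 6.14, where 11 of 24 other probes of the title were also at least 2-fold higher and 3 at least 2-fold lower. A MADS box protein PIa (BE659710.1_418), of a family of developmental transcription factors, was higher by 6.08.

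The largest difference downward was a xylem-specific cellulose synthase, titled CesA3 of poplar (AW279531.1_451, log2 difference -8.56, 377-fold lower). Its unscaled signal was 366 at 51 DAF and 15.8 at 66 DAF. Further cellulose synthases, the subunit 6 title (AI438079.1_383, -7.91) and CesA2 of poplar (CX703131.1_676, -7.01), were also among the 8 lowest. The others were a phospholipase D (BU080965.1_358, -8.47), a resistance protein candidate (BE801380.1_361, -7.93) and an isoflavonoid methyltransferase, D7OMT (AW733746.1_535, -7.62), whose single other probe was higher. A title of an ultrahigh sulfur keratin-associated protein, of unclear meaning in a plant, stood at -7.53 (BF066985.1_93). A multicopper oxidase, of the family that holds the laccases (GMFL01-36-A09-R_387), stood at -6.79, and of 18 other probes of its title 10 were lower and 2 higher. The sizes depended on the background correction: with normexp these 8 probes stood between -5.42 (CesA3) and -4.43 (D7OMT), and the 8 largest differences upward between 4.60 (PE3 and PIa) and 7.08 (TSJT1).

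Many more probes were above background at 66 DAF alone than at 51 DAF alone, 10522 against 264. Of the former, 1505 were at least 2-fold higher at 66 DAF by their bound, a number that was 262 with normexp background correction and 3066 with loess normalization. All 264 of the latter were at least 2-fold higher at 51 DAF. That count follows largely from the floors, -2.62 at 51 DAF and -6.44 at 66 DAF in normalized log2. With spike-in scaling 10521 probes at 66 DAF alone and 28 at 51 DAF alone were at least 2-fold higher. The largest bounds at 66 DAF were the trypsin inhibitor p20 (CF920954.1_716), a protease inhibitor and at least 1339-fold higher, and CPRD2, a cowpea gene by its title (CF805949.1_377, at least 617-fold). A reticuline oxidase (CF921380.1_572) was at least 581-fold higher, with 4 of 7 other probes of its title also higher and 1 lower. A beta-glucosidase (BI968800.1_562) was at least 411-fold higher, with 1 of 15 other probes higher and 3 lower. At 51 DAF alone the largest bounds belonged to a kinesin of the KAR3 subfamily, a microtubule motor (GMFL01-02-L15-F_651, at least 190-fold higher at 51 DAF, with 5 of 9 other probes the same way and 1 opposite). A multicopper oxidase (BI784526.1_434) was at least 178-fold higher at 51 DAF, with 11 of 19 other probes the same way and 2 opposite. The auxin down-regulated ADR12 (AI461172.1_264) was at least 161-fold and a protein similar to potato p322 (GMFL01-31-N04-R_248) at least 143-fold higher at 51 DAF. These bounds depended on the processing as well. For p20 the log2 bound was 10.39, against 8.51 with normexp background correction and 12.18 with quantile normalization. With normexp the other 3 at 66 DAF stood between 6.86 and 7.20, and the 4 at 51 DAF between -4.21 and -4.10.

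Monolignol synthesis had a median log2 difference of 1.41 (95% interval over probes 0.26 to 1.83), at percentile 100 of the random lists. Over all 88 probes without a filter on signal 38 were higher and 32 lower, with a median of 0.29 (-0.78 to 1.36). The members with the largest differences upward were a phenylalanine ammonia-lyase, the entry enzyme of the pathway (BI972321.1_503, 3.21), and the 4-coumarate:CoA ligase 4CL1, which activates the acids (AI938631.1_114, 3.10; GMFL01-26-C13-R_365, 2.98). The isoenzyme 4CL3 held the 3 largest differences downward (CF921704.1_755, -5.25; CO980757.1_690, -4.32; AW348182.1_160, -3.50). A breakdown by enzyme was made after the values were seen. Of 11 phenylalanine ammonia-lyase probes 6 were measured, and all 6 were at least 2-fold higher, with a median of 1.99. The same held for all 4 probes of 4CL1 (2.85) and for both measured probes, of 5, of hydroxycinnamoyl transferase (2.39). It also held for the 4 measured probes, of 5, of the hydroxylase CYP98A2 (1.91). Of 8 cinnamate 4-hydroxylase probes 6 were measured and 4 were higher (1.31). Among 6 measured probes of 4CL3, 5 were lower and 1 higher, with a median of -3.06, and 1 more was at least 2-fold higher at 51 DAF alone. The last steps were mixed: cinnamyl alcohol dehydrogenase, which makes the alcohols, had 3 of 4 measured probes higher (1.47), of 11 in all. Another 1 of its probes was at least 2-fold higher at 51 DAF alone. Caffeic acid O-methyltransferase had 1 of 4 lower, with a median of -0.27 that became 0.11 under median centring. The single measured probe of a cinnamoyl-CoA reductase title stood at 0.26, with values from -0.0085 (quantile normalization) to 1.15 (normexp background correction) under other scalings. The 12 family titles of that reductase, which belong to the flavonoid list as well, had 5 higher and 2 lower, with a median of 0.06 that was -0.16 with normexp background correction.

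**Figure D2:**
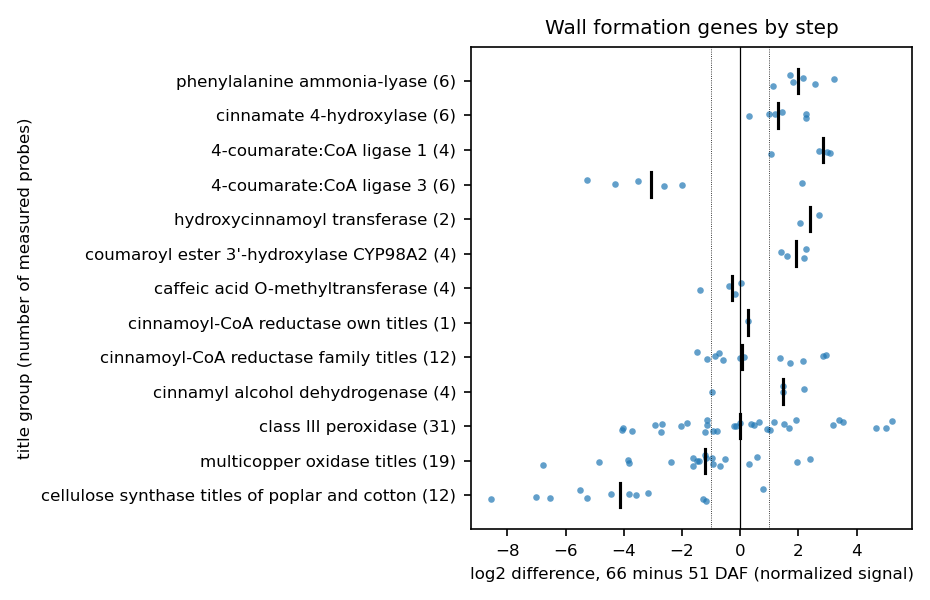
Log2 difference 66 minus 51 DAF of each measured probe (points) and the median (bar) for enzymes of wall formation, relative to each array's 75th percentile, with dotted lines at 2-fold. The early monolignol enzymes lie on the higher side except 4CL3 (median -3.06), peroxidases spread to both sides, and cellulose synthase titles of poplar and cotton lie on the lower side (-4.14); spike-in scaling would add 4.83 to every value.

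Lignin polymerisation, the oxidative coupling of monolignols by peroxidases and laccases, went both ways among probes measured on both arrays. Of 34 measured probes 12 were higher and 11 lower, with a median of 0.09 (percentile 75.3) that became -0.05 with normexp background correction. Peroxidases went both ways: Prx4 (GMFL01-51-L21-R_392, 5.22), peroxidase 1A (AI938069.1_163, 5.01) and px12 (BU548599.1_309, 4.68) led upward. Prx2 (GMFL01-20-J05-R_159, -4.06), px1 (AW666227.1_491, -4.02) and FBP5 (BG510761.1_407, -3.72) led downward. A further 12 members were measured at 66 DAF alone and at least 2-fold higher there, and 2 at 51 DAF alone. Over probes above the common floor on either array, with lower values raised to that floor, 24 of 51 were higher and 11 lower, with a median of 0.93 (0.0018 to 1.93) at percentile 100. None of the 4 probes with a laccase title was measured on both arrays. In the breakdown made after the values were seen, multicopper oxidase titles, which were not in the list, had 11 of 19 probes lower and 2 higher, with a median of -1.19.

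Secondary wall polysaccharide genes had a median of -1.63 (-3.06 to -0.93), at percentile 0.01. The 3 cellulose synthases named above (-8.56, -7.91 and -7.01) led downward, while a cellulose synthase isolog (BE440307.1_506, 3.75, with its single other probe lower) and catalytic subunit titles (GMFL01-02-J06-R_248, 2.82-fold; BQ743073.1_478, 2.80-fold) were the 3 members that were higher. With normexp background correction BQ743073.1_478 stood at 0.77. Cellulose synthase titles in the list do not all separate primary from secondary walls. The subunit 6 probe is thus not shown to be a secondary wall gene, and its single other probe did not differ 2-fold. In the breakdown made after the values were seen, cellulose synthase titles of poplar and cotton had 11 of 12 probes at least 2-fold lower, with a median of -4.14. Cambium and xylem identity genes had a median of -1.32 (-1.93 to -0.85), at percentile 0.19. Besides CesA3, which both lists hold, the lowest were the class III HD-Zip factor HB4, of a family that patterns vascular tissue (BI498095.1_281, -4.41), and the homeodomain-leucine zipper protein Hdl57 (BU763776.1_505, -3.44). HB6 of the same HD-Zip class was the single member that was higher (GMFL01-10-M02-R_120, 1.72; 0.17 with normexp background correction). Phloem proteins had all 4 measured probes lower, with a median of -2.04 (percentile 0.85), led by phloem specific protein titles (-2.82 and -2.17). With correction for the probe source 2 of the 4 were lower, with a median of -0.98 at percentile 5.24, and with identical titles averaged the percentile was 4.52. With the stricter filter on signal the secondary wall median was -0.26 at percentile 15.0, and with normexp background correction the xylem identity median was -0.95 at percentile 5.78.

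Aquaporins had a median of -0.22 (-1.51 to 0.53), at percentile 85.9, and the median turned to 0.16 under median centring, with 10 higher and 12 lower. Leading upward were the plasma membrane channel Pip1 (GMFL01-04-H06-F_409, 4.01-fold), for which 1 of 3 other probes was higher and 2 lower. A water-stress induced tonoplast channel (BE555107.1_83, 1.65) and NIP2 (GMFL01-17-I05-R_425, 1.59) followed, with values of 0.10 and 0.35 under normexp background correction. An aquaporin titled after tung tree (GMFL01-20-G19-R_420, -4.55), the tonoplast channel RB7-5A, named root-specific (BI973241.1_407, -4.14), and the nodulin-26-like mip4 (GMFL01-41-I07-R_346, -4.02) led downward. Among members above a floor common to both arrays the median was 0.46.

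Genes of cell wall loosening and separation had 37 of 70 probes lower and 17 higher, with a median of -1.38 (-2.02 to -0.23), at percentile 0.08. Both directions held large differences. The pectinesterases named above (7.20 and 6.31) and the xyloglucan endotransglycosylase XET02 (BE555202.1_300, 3.93), which remodels hemicellulose, led upward. A pectate lyase, which cleaves pectin (BE803992.1_127, -6.11), the pectin methylesterase pme2 (GMFL01-10-B17-R_550, -5.06) and a pectinesterase (GMFL01-49-G06-R_287, 31.9-fold lower) led downward. The direction of the median depended on the filter: it was 0.87 (percentile 98.9) with the stricter filter and 0.11 with a common floor, filters that also remove a probe because it was low at 66 DAF. The list stayed below the random lists in 10 of 14 alternatives, and its percentile was 6.04 with identical titles averaged and 7.21 with either array. Genes of wax, cutin and suberin had 3 of 21 higher and 7 lower, with a median of -0.54 (percentile 35.3).

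Photosynthesis had a median of 1.72 (1.44 to 2.01), at percentile 100, with 71 probes higher and 20 lower. Over all 211 probes without a filter on signal 93 were higher and 88 lower, with a median of 0.40 (-0.86 to 1.07). Rubisco activases, which keep the carbon-fixing enzyme active, stood at 5.35 (Rca1, GMFL01-15-M13-R_554) and 4.10 (Rca, GMFL01-14-G09-R_157), and the Rubisco small subunit rbcS1 at 4.20 (BE800817.1_243), with all 7 of its other probes higher. A photosystem II 5 kD protein (BI424207.1_81, -5.50), a photosystem I reaction centre title (CK605543.1_367, -5.30) and a photosystem II W protein (BE807265.1_124, -4.76) led downward. Genes titled as senescence genes had 4 of 33 higher and 14 lower, with a median of -0.65 (percentile 50.4) that turned to 0.63 with the stricter filter, 0.45 with a common floor, and 0.017 both with either array and with wrongly matched members removed. The stay-green protein SGR1, which acts in the breakdown of chlorophyll, was the highest (GMFL01-40-B23-R_276, 2.75), and a senescence-induced receptor-like kinase the lowest (BI427061.1_392, -4.18). Autophagy genes had 2 of 17 higher and 3 lower, with a median of -0.08 (percentile 59.9). Cell death proteases and nucleases had 14 of 43 higher and 9 lower, with a median of 0.06 (percentile 58.5). Cysteine proteinases led upward (GMFL01-04-O01-F_722, 2.64; BU578618.1_335, 2.45; GMFL01-30-I21-R_308, 2.38; BU578618.1_335 was just under 2-fold with normexp background correction), and a metacaspase downward (BE057373.1_480, -4.19).

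Among the hormone lists, auxin genes were lower, with 44 of 82 probes lower, 11 higher and a median of -1.07 (-1.36 to -0.55), at percentile 0. The auxin-conjugating GH3.12 (CA801027.1_495, -6.24), the response factor ARF2 (BU578386.1_426, -5.62) and the influx carrier AUX1 (CD416427.1_505, -5.14) led downward. An auxin-induced protein (AW397551.1_329, 3.29), ARG-2 (BE821504.1_484, 2.56) and Aux28 (BE661239.1_468, 2.51, with 3 of 6 other probes lower and 1 higher) led upward. Abscisic acid genes had 8 of 21 higher and 6 lower, with a median of -0.52 (percentile 9.40) that was 0.30 with normexp background correction. All 3 of the largest differences downward were NCED1, the rate-limiting enzyme of abscisic acid synthesis (GMFL01-35-D22-R_142, -5.06; BM085005.1_457, -3.36; GMFL01-02-C22-R_126, -3.33), and an ABA-responsive protein was the highest (BE475172.1_444, 3.20). Ethylene genes had 9 of 31 higher and 5 lower, with a median of 0.40 (percentile 91.2). The response factor EREB stood at 2.85 (BF423994.1_536). An oxidase of the ethylene precursor ACC stood at 2.52 (GMFL01-29-M05-R_374; 0.69 with normexp background correction) and another at -2.13 (GMFL01-46-B11-R_382), and an ACC synthase stood at -2.12 (GMFL01-17-O11-R_475).

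Flavonoid and isoflavonoid synthesis was higher, with 31 of 59 probes higher, 14 lower and a median of 1.39 (-0.11 to 2.14), at percentile 100. A reductase of deoxychalcone synthesis (CX548207.1_312, 4.55; GMFL01-12-C01-R_368, 4.29) and a chalcone synthase, the entry enzyme of the branch (GMFL01-07-F16-R_569, 4.50), led upward. A 6-deoxychalcone synthase title (AW830748.1_250, -4.32) led downward. By their titles this synthase and the reductase that led upward appear to be the same enzyme, so probes named after it disagreed in direction. The median was -0.32 over all probes without a filter on signal. Pathogenesis related proteins had 21 of 47 higher and 10 lower, with a median of 0.41 (percentile 97.0) and 9 more at least 2-fold higher at 66 DAF alone. The list lay above the random lists in 9 of 14 alternatives, with a median of up to 2.05 (stricter filter), while without a filter the median was -0.74 (percentile 79.6). Besides MDTL1, an endo-1,3-beta-glucanase (CO984885.1_778, 5.68) and the chitinase Chia1 (CO981370.1_773, 5.34), which attack fungal walls, led upward. A predicted chitinase was the lowest (AW350972.1_632, -3.94, with 2 of 3 other probes higher).

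Among the transcription factors, NAC genes, a family that includes regulators of vessel formation and of senescence, had 6 of 27 higher and 9 lower, with a median of -0.16 (percentile 39.7). NAC1 (CA852016.1_732, 3.99), NAC2 (GMFL01-34-G08-R_288, 3.54) and NAC3 (AW119422.1_302, 3.20) were the highest, and ANAC029 was the lowest (AW705917.1_529, -5.10). MYB factors had 7 of 49 higher and 17 lower (median -0.31, percentile 48.5), and WRKY factors had 7 of 38 higher and 16 lower (median -0.49, percentile 21.6).

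Amino acid remobilisation had 33 of 83 higher and 17 lower, with a median of 0.35 (-0.12 to 1.05, percentile 97.0) and 17 more at least 2-fold higher at 66 DAF alone. At 4-fold 7 were higher and 12 lower, and the list lay above the random lists in 9 of 14 alternatives. A glutamine synthetase, which assimilates ammonium, stood at 3.71 (AW761454.1_191, with its single other probe lower), the permease AAP3 at 3.25 (BQ630326.1_461) and an allantoinase at -4.52 (AW831253.1_344). Sugar transport and sucrose breakdown had 14 of 44 higher and 10 lower, with a median of 0.24 (percentile 86.4), and at 4-fold 5 were higher and 6 lower. The monosaccharide transporter stp1 (CO985102.1_22, 4.37) and a cell wall invertase, which splits sucrose outside the cell (AW350518.1_578, 3.86), led upward, and the sucrose transporter sut1 downward (GMFL01-17-K15-R_559, -3.83). Cytosolic ribosomal proteins had 85 of 318 higher and 22 lower, with a median of 0.58 (0.43 to 0.66), at percentile 100. With normexp background correction 181 were higher and 18 lower, with a median of 1.15, and without a filter on signal 114 of 476 were higher and 129 lower, with a median of 0.29. Proteasome and ubiquitin genes had 41 of 122 higher and 11 lower, with a median of 0.46 at percentile 99.2. The percentile was 94.8 among random lists of titled probes, 89.8 with correction for the probe source and 96.2 with the stricter filter.

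Cell cycle genes had 15 of 52 higher and 13 lower, with a median of 0.20 (percentile 94.0). Histone H4 (GMFL01-19-B02-R_432, 2.68) and the replication factor PCNA (CX710851.1_787, 2.05) were the highest, and histone H2A.FZ followed at 1.57 (BG352694.1_300). With normexp background correction PCNA stood at 0.64 and H2A.FZ at -0.057. The mitotic kinase CDKB (CD402746.1_508, -5.38) and the cyclins d3 (CD417852.1_492, -3.46) and d2 (BE823845.1_353, -3.42) were the lowest. Tubulin and actin genes had 12 of 67 higher and 24 lower (median -0.25, percentile 21.4). Heat shock proteins and chaperones had 45 of 197 higher and 54 lower (median 0.01, percentile 92.2), and LEA and dehydration proteins 8 of 53 higher and 12 lower (median -0.14, percentile 37.7). With spike-in scaling left aside, 9 lists had a median whose sign changed under another scaling between arrays or background correction. All of them lay within the middle 95% of random lists. Besides those named as such they were autophagy, LEA and dehydration proteins, heat shock and chaperones, NAC factors, MYB factors, and tubulin and actin. A further 10 lists turned, apart from spike-in scaling, only with a filter, a correction or another membership: wall loosening, senescence, cell death proteases, flavonoid synthesis, pathogenesis related, WRKY factors, sugar transport, cell cycle, seed and nodule proteins.

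Among the lists of other tissues, vegetative storage and pod wall proteins were lower at 66 DAF, and few seed proteins were measured on both arrays. Of 92 seed protein probes 4 were measured on both arrays, with 1 higher, 3 lower and a median of -2.29 (percentile 13.3), and 28 were above background at 66 DAF alone, 9 of them at least 2-fold higher by their bound (24.6% of all probes were above background at 66 DAF alone). The median turned to 1.55 (percentile 94.4) with a common floor, 5.44 (percentile 99.3) with the stricter filter, which left 1 probe, and 2.69 (percentile 100, 10 of 14 higher) with either array. The Kunitz trypsin inhibitor KTi3 stood at 5.44 (GMFL01-20-I23-R_498) and the inhibitor Ti-b at -3.72 (GMFL01-10-G17-R_542). Vegetative storage and pod wall proteins had 22 of 35 lower and 5 higher, with a median of -1.50 (percentile 0.32), or -2.49 at percentile 43.9 without a filter on signal. The lipoxygenase vlxC led downward (GMFL01-14-E16-R_712, -5.40). Nodule proteins had 10 of 23 lower and 6 higher, with a median of -0.82 (percentile 2.02) that was 0.025 with the stricter filter and 0.051 with a common floor, and the list stayed below the random lists in 4 of 14 alternatives. The early nodulin N-75 was the highest (BG155375.1_289, 4.17) and ENOD40-2 the lowest (GMFL01-40-F18-R_321, -3.65).

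In total 12 of 31 lists lay outside the middle 95% of their random lists, where 1.55 are expected by chance for independent probes. The 5 above were monolignol synthesis, photosynthesis, flavonoid and isoflavonoid synthesis, cytosolic ribosomal proteins, and proteasome and ubiquitin. The 7 below were secondary wall polysaccharides, wall loosening, auxin, vegetative storage, nodule, phloem, and cambium and xylem identity. Probes of a list are not independent, and the rank holds for this pair of arrays.

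**Figure D3:**
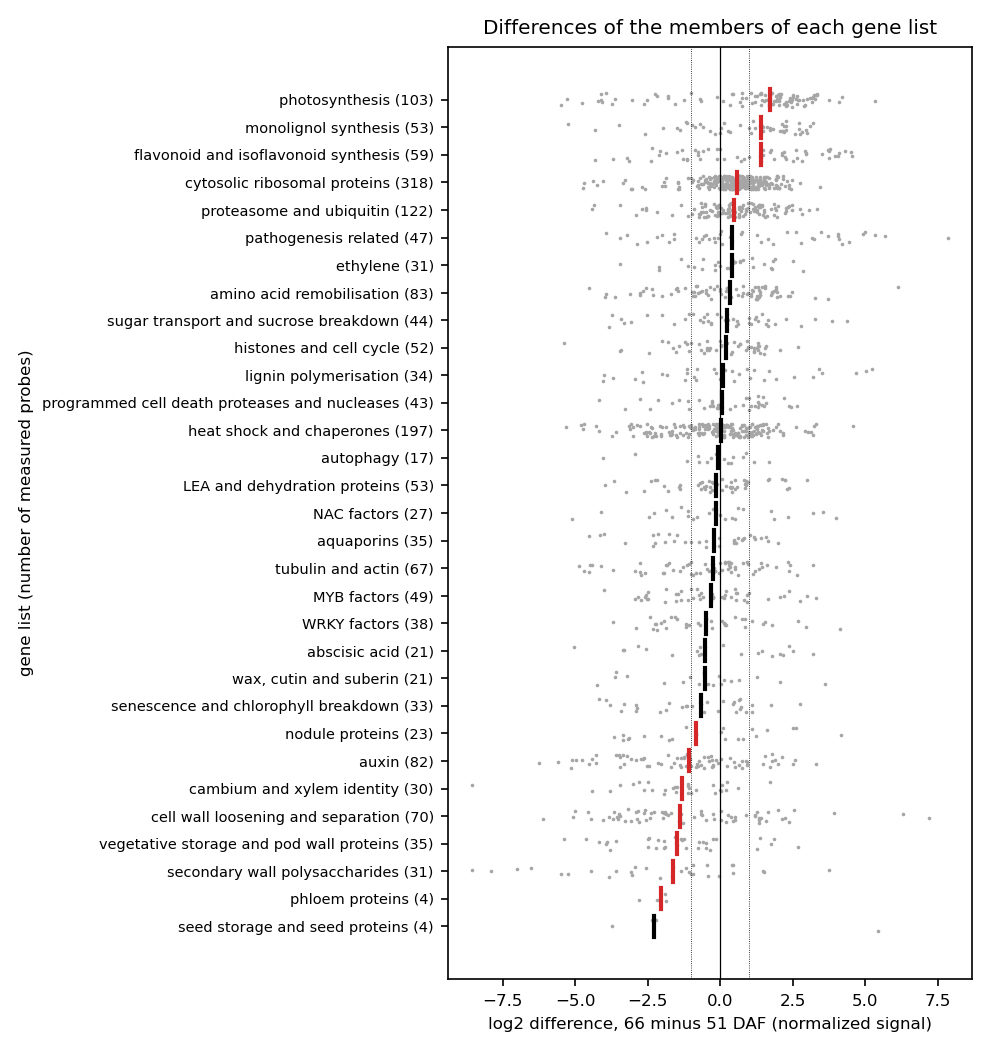
Log2 difference 66 minus 51 DAF of each measured probe (points) and the median (bars) of the 31 gene lists, relative to each array's 75th percentile, with dotted lines at 2-fold and bars in red where the median lay outside the middle 95% of 10000 random lists. Photosynthesis (1.72), monolignol (1.41) and flavonoid synthesis (1.39) lie highest; the wall loosening and nodule medians turn positive with the stricter filter, and spike-in scaling would add 4.83 to every value.

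Titles of genome repeats and organelle genomes, grouped after the values were seen, differed from the messenger RNA titles. All 6 measured satellite repeat probes were lower at 66 DAF, with a median of -6.10, and 37 of 42 retrotransposon probes were lower, with a median of -3.99. Mitochondrial genome titles had 7 of 7 lower (median -3.61), nuclear ribosomal RNA titles 4 of 4 lower (median -3.78) and plastid genome titles 8 of 12 lower (median -1.77). DNA transposase titles had 5 of 12 lower and 2 higher (median -0.60). Fungal titles had 11 of 23 lower and 2 higher (median -0.98). Before scaling, 780 of the 22667 measured probes (3.44%) were brighter at 51 DAF, and 250 were brighter there by more than the spike-ins.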

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

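All tests in this part were chosen after the results were seen. The spike-in spots, which enter no comparison of genes, were brighter at 51 DAF while the soybean probes were dimmer, with a mean log2 difference of -0.80. They stood out because they are a signal outside the main measurement that went against it.

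The median measured soybean probe was dimmer at 51 DAF by 3.81 log2 units. Weaker hybridisation, washing or scanning would dim the spike-ins too, and their difference of -0.80 argues against it as the whole cause. A smaller share of messenger RNA behind the labelled 51 DAF material may have contributed, since ribosomal RNA and mitochondrial titles differed by 0.42 (-0.48 to 1.12) between the arrays, although plastid genome titles differed by 2.26 (1.38 to 3.40). Genomic DNA in the 51 DAF material, taken up below, could also give the small difference of 0.42, so these titles do not separate the accounts. Degradation of the 51 DAF RNA stays open. Titles of 5' ends stood below those of 3' ends by -0.87 (-1.28 to -0.32), where a loss of 5' ends at 51 DAF would give the opposite sign. Only probes measured on both arrays enter that difference, 67 of them with 3' titles, so lost probes are left out and its sign cannot decide. Of the probes seen at 66 DAF, 42.4% of the 5' and 31.6% of the 3' titles were missing at 51 DAF, the other way. Among clone reads seen at 66 DAF, 452 of 1356 forward (33.3%) and 1001 of 7155 reverse reads (13.99%) were missing at 51 DAF. Less messenger RNA in the pedicel itself at 51 DAF, which would account for the same gap of 4.60 between the measured probes and the spike-ins, cannot be told apart from handling or degradation with 1 array per time point.

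Repeat and organelle titles stood out on the 51 DAF array. The scaling of a dim array is not enough, because satellite titles lay below the spike-ins even without scaling, by -1.27 (-1.72 to -0.69). Genomic DNA in the 51 DAF material is a candidate explanation, since the satellite titles had an unscaled difference of -2.07 (-2.52 to -1.49) while DNA transposase titles stood at 3.43 (1.77 to 5.00). Plastid genome titles, however, had an unscaled difference of 2.26 (1.38 to 3.40). Copy numbers of these titles were not measured. Transcription of retroelements at 51 DAF stays open as well, because the retroelement titles alone, at 0.044 (-0.96 to 1.42), do not separate transcript from DNA. Of the 250 probes that were brighter at 51 DAF by more than the spike-ins, 22 had a genome or organelle title and 108 named another product.

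Monolignol and photosynthesis probes were higher and secondary wall and xylem identity probes lower at 66 DAF, with a contrast of medians of 3.12 (2.52 to 3.61) over 156 and 60 probes. Corrections argue against the GC content of the probes (contrast 3.11 after correction, 2.51 to 3.64) and the transcript end of the probes (2.89, 2.29 to 3.42) as the whole cause. Above a common floor the contrast was 2.73 (1.96 to 3.14), which does not decide the part of the dim array's floor. That common floor is the 51 DAF floor, so it removes only probes low at 66 DAF. The higher lists keep all members counted as higher, with medians of 1.42 (monolignol) and 1.92 (photosynthesis). The pooled contrast does not settle the part of the floor in the lower lists alone. Above a common floor the secondary wall median was -0.93 (-2.06 to 0.42), at percentile 0.14. The xylem identity median there was -1.10 (-1.53 to -0.00016), at percentile 0.01. Development of the pedicel between 51 and 66 DAF may underlie the contrast of 3.12, but with 1 array per time point it cannot be told apart from a difference between plants or in handling.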

How the results depend on the processing

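The alternatives of a common floor, either array, GC content, probe source, removed members, titled random lists and averaged titles were chosen after seeing the data. No paired analysis was possible because each time point had 1 array, and leaving out a replicate was not possible for the same reason. The mean over the probes of an accession changed nothing by construction, since each accession had 1 probe. The dim 51 DAF array set the limit on signal over background, with 22937 probes above it against 33194 at 66 DAF.

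The 4194 higher and 7257 lower probes became 21672 and 69 with spike-in scaling, which adds 4.83 log2 to each difference. They became 7608 and 19331 without a filter. With the stricter filter 2829 were higher and 2123 lower, so that 57.1% of the differing probes were higher. The lower probes became 3757 with a common floor. The stricter filter and the common floor also remove a probe because it was low at 66 DAF. The common floor left the higher probes at 4194 by construction, since it can remove only probes low at 66 DAF. The higher probes were 6294 at 1.5-fold, and 1354 were higher and 4076 lower at 4-fold. The 1505 probes at least 2-fold higher at 66 DAF alone became 262 with normexp background correction and 3066 with loess normalization, and the cause was not tested. Without a filter the median was -1.76 for lignin polymerisation and -1.72 for aquaporins, with probes at the floor included.

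Of the list medians under alternatives, 372 stayed within their interval over probes, 57 moved out of it with the same sign or without a call, and 5 turned. A turn was counted only for lists outside the random lists, so sign changes of the other lists are among the 372 and the 57. Of the 372, 31 came from the mean over the probes of an accession, which could change nothing. The 5 that turned were wall loosening (0.87 with the stricter filter, 0.11 with a common floor), nodule proteins (0.025 and 0.051 with the same alternatives) and flavonoid synthesis (-0.32 without a filter), and the cause was not tested. For monolignol synthesis, lignin polymerisation and aquaporins, the lists for which this was counted, member counts beyond 2-fold stayed within 1.5-fold of the reported count in 38 of the cases upward and 35 downward, and moved further in 10 and 13. Of the single-gene values, 462 moved by no more than the scanner's error of the difference, 693 moved further with their sign kept and 1 turned. The histone H2A.FZ probe BG352694.1_300 was -0.057 with normexp background correction. Lists above the random lists numbered 8 without a filter, 8 with the stricter filter and 9 with either array, against 5. Those that came to lie above in at least 1 alternative were pathogenesis related and amino acid remobilisation (9 of 14 each), seed proteins and cell cycle (2 each), and lignin polymerisation, ethylene, cell death proteases and wall loosening (1 each). Lists below numbered 4 with the stricter filter and 4 with averaged titles, against 7, and the cause was not tested. Of the 12 lists outside, between 8 (stricter filter) and 12 (median centring) stayed outside on the same side. Median centring shifts every difference alike, so it cannot change a rank, and its 12 was fixed by construction. It and the mean over the probes of an accession both count among the 14 alternatives. The monolignol median stayed positive, from 0.29 without a filter to 1.80 with GC correction, at percentile 100 in each alternative that ranked lists. The GC correction also re-centred the differences, so the rise to 1.80 cannot be credited to GC content alone. All 16 named genes measured on both arrays kept their direction beyond 2-fold under the 5 alternatives of background correction, normalization and authors' values and under GC correction, and so did the 8 measured on 1 array under those 5. These genes were chosen for the largest differences or bounds on the same arrays, so they were likely to keep their direction.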

Other observations

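The values in this part were computed after the arrays had been seen. Read end, stated transcript end and GC content also entered the tests above, and no other explanation of these values was tested. Probes made from forward reads of the clone collection had a median log2 difference of -1.01 over 904 measured probes, and those from reverse reads 0.21 over 6153. Probes whose title states the 5' end of a transcript had a median of -0.86 over 3143 measured probes, with 1506 at least 2-fold lower and 402 higher, against 0.00 over 67 probes that state the 3' end. The difference fell slightly with the GC content of the probe, with a Spearman correlation of -0.15 across 22667 probes, which are not independent replicates.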
